A study of Danio rerio with 12 samples.

How the data were processed

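Total RNA from 12 pools of 40 zebrafish embryos was measured, 1 pool per array, on 1-colour NimbleGen expression arrays labelled with Cy3. Embryos were exposed from 48 hours post fertilization (hpf) to 10 µM trimethyltin (TMT), an organotin compound known as a neurotoxicant, or to vehicle, and collected at 60 or 72 hpf, which gives 4 groups of 3 pools. The labels give an incubation temperature of 37 °C, which is well above the usual rearing temperature of zebrafish, and this was not resolved here. Groups and replicate numbers were taken from the sample titles.

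The deposited values are intensities on a linear scale, 1 per feature and array, that the authors obtained with RMA, per the submitters' processing notes. RMA corrects background, normalizes arrays to a common distribution and summarises the probes of a feature. Its version, settings and software are not given in the sources used here. Per the file headers, each value stands for a feature of up to 3 probes. Of the 38489 features, 36632 had 3 probes, 1796 had 2 and 61 had 1, and 1380 were reverse-orientation features. The authors' series table held the same intensities, since all 461880 of its values equalled those of the arrays' own files. The only control entry, the summary of 24055 random-sequence probes, was left out of every test and used as a measure of background. No slide or scan date was used here, so no batch was fitted.

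Intensities were converted to log2 with no pseudocount, no further normalization and no filter on dim features. Features were named in the following order. RefSeq accessions were matched without version for 2663 of 3055 accession features, a gene number named 2117 further features, the file's symbol matched a current or older symbol for 10058, and the file's symbol was kept as written for 2128. In all, 16966 features had 1 gene symbol, covering 12591 genes, and 21523 had none. The reference table of the GRCz12tu assembly was used for names only, and coordinates are those of the files, in the Zv7 build.

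Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on log2 intensities of all 12 arrays in 1 fit with a mean per group, which leaves 8 residual degrees of freedom. The contrasts were TMT minus control at 60 hpf and at 72 hpf, the difference between these 2 effects, and control 72 minus 60 hpf. P-values were adjusted over the 38489 features by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. Unless another test is named, every adjusted p of a gene is limma's. The number of arrays per group limits the precision, and the median standard error of a TMT effect was 0.272 log2 units. The labels do not say that the pools came from separate clutches, so p-values measure only the spread between these pools. With 1 array left out, its group held 2, and the spread was still shared over all groups.

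Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with 1 feature per gene (the highest mean log2 intensity over the 12 arrays), adjusted over the 37 lists of a contrast, and again with an estimated correlation. In the text, a list rose or fell when its adjusted p at the preset correlation was below 0.05. The lists covered heat shock proteins, metallothionein and metal response, oxidative stress, endoplasmic reticulum (ER) stress and amino acid starvation, p53 targets and apoptosis, immediate early genes, inflammation, neutrophils and macrophages, erythroid cells, vascular endothelium, ADP-ribosylation factors, hypoxia, glycolysis, oxidative phosphorylation, photoreceptors, lens, pigment cells, synapse and mature neurons, neural progenitors, glia, skeletal muscle, cardiac muscle, cartilage and bone, extracellular matrix, epidermis and ionocytes, liver, pancreas, intestine and yolk lipid transport, kidney, retinoid and RXR/PPAR targets, cholesterol and fatty acid synthesis, xenobiotic response, cell cycle, cytosolic ribosomal proteins, proteasome, circadian clock, and the stress hormone axis. They held 745 measured genes, of which 16 stood on more than 1 list. Counts of list members were also taken with p-values adjusted over the list alone. This adjustment does not account for the number of lists, so single passes under it can arise by chance.

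Named genes were chosen by a rule. It takes, for each TMT contrast, the 12 called genes with the largest rise and the 12 with the largest fall whose 3 treated and 3 control values did not overlap (10% of features by chance) and whose feature had 1 non-provisional symbol. It further takes the 6 largest each way of the difference between the effects, the 8 largest each way of the control ages, up to 4 members of each list with the smallest adjusted p in each TMT contrast, and every measured ADP-ribosylation factor of its list. The groups, contrasts, tests, lists, this rule and all alternatives but 1 were fixed before the data were examined.

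The alternatives were the arrays of the compared groups alone, the replicate number as a block, the series table, a further quantile normalization, centring on array medians, only features above the median signal, eBayes with trend and robust moderation, array weights, 1 feature per gene, a change of at least 2-fold, each array left out, and for the lists an estimated correlation and the mean of a gene's features. The log2 level of the random probes as a covariate was added after seeing the data.

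The steps were tested on simulated data with the real features' means and spreads and 200 changed features, 50 per size. At 60 hpf, 8 of 50 changes of 1 log2 unit, 39 of 50 of 2 units and 48 of 50 of 3 units were called. At 72 hpf these were 12, 38 and 47, for the difference of the effects 0, 19 and 38, and for the control ages 8, 36 and 46. No call had the wrong sign, and there were 7, 3, 3 and 7 false calls. Among 37 simulated lists of 20 genes each, both lists shifted by 0.5 were found at each age, and both shifted by 0.25 at 72 hpf but only 1 of 2 at 60 hpf, with none of the 33 unshifted lists called. Noise was drawn independently for each gene and the lists were random. The simulation therefore cannot show how often lists of genes that vary together are falsely called. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.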

Results

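Gene expression was profiled in whole zebrafish embryos exposed to TMT or vehicle from 48 hpf, after 12 h of exposure at 60 hpf and after 24 h at 72 hpf. Each of the 4 groups held 3 pools of 40 embryos. Median intensities were close across the 12 arrays, from 1012 to 1176. The random-sequence probes, which measure background, gave intensities of 81.7 to 138 per array, and 90.2% to 98.9% of the 38489 features lay above that level. The lowest background was in TMT pool 2 at 72 hpf and the highest in control pool 2 at 60 hpf. Pearson correlations across features ran from 0.944 to 0.975 between arrays of a group and from 0.928 to 0.980 between arrays of different groups. The median standard deviation of a feature was 0.338 log2 units in the 60 hpf controls, 0.269 after TMT at 60 hpf, 0.254 in the 72 hpf controls and 0.296 after TMT at 72 hpf.

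The comparison at 60 hpf asked which transcripts responded to the shorter exposure. A single transcript rose, an expressed-sequence contig that the array design lists as TC252426 and describes as similar to human ADP-ribosylation factor 1, a small GTPase of vesicle traffic. It has no gene symbol or coordinates in the files and was singled out after its values were seen. Its log2 intensity was 10.43 ± 0.12 in control and 13.05 ± 0.09 in TMT pools (SD, n = 3), a 6.14-fold rise (log2 2.62, SE 0.20, adjusted p = 0.00038). Without control pool 1 the count of features was 2, and the contig kept its call with each array left out in turn. The stress transcription factor gene ddit3 was 0.87 log2 units and the calcium channel gene trpv6, expressed in ionocytes, 1.02 log2 units above control. Neither passed over all features (adjusted p = 1 for each). Each passed with p adjusted over the list alone (0.00566 on the ER stress list and 0.0118 on the epidermis and ionocyte list). These were the only such passes at 60 hpf. That adjustment does not account for the 37 lists tested, so a few such passes can arise by chance alone. They do not show an early response of either gene.

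Of the gene lists, that of neural progenitors fell at 60 hpf. Its median log2 effect was -0.13 over 21 genes, 18 of them below control (camera adjusted p = 0.00889, and adjusted p = 0.729 with an estimated correlation). None of its members passed alone, over all features or adjusted over the list alone. Among its members, the Notch ligand gene dla stood at -0.61 (adjusted p = 1). Without control pool 3 this call was lost (adjusted p = 0.239). The number of lists called was 6 without control pool 2, 2 without control pool 3, 5 without TMT pool 1 and 2 without TMT pool 2. The other 36 lists were not called, with photoreceptors (median 0.12, adjusted p = 0.1) nearest to the threshold. In limma's test 837 features had an unadjusted p below 0.05 at 60 hpf, 374 higher and 463 lower, where chance alone would give 1924. A shortfall of this kind is possible where arrays of different groups share deviations, and its cause was not tested. The low count thus does not show that TMT had no effect at 60 hpf.

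At 72 hpf, after the longer exposure, stress-response transcription factors were among the transcripts with the largest rises. They included atf3, which stress signals induce (14.2-fold), the AP-1 subunit fosl1a (8.90-fold) and the activating transcription factor atf5a (7.12-fold). Transcripts of the cone opsins opn1mw1, opn1sw2 and opn1lw2 and of the opsin kinases grk7a and grk1b fell, and the green opsin opn1mw1 was 4.64-fold lower. The cone opsin opn1sw1 (log2 -0.98, adjusted p = 0.0891) was not called. Of 38489 features, 331 rose and 86 fell, and 301 and 72 of these changed at least 2-fold. At an unadjusted p below 0.05, 2183 features were higher and 2246 lower, and among the calls the balance moved to 749 higher and 618 lower with array weights. The 417 calls of the main fit included 178 features with a symbol, from 161 genes.

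The contig similar to ADP-ribosylation factor 1 again had the largest change of the named features, from 10.70 ± 0.27 to 15.59 ± 0.22 (SD, n = 3), a 29.5-fold rise (log2 4.88, 95% interval 4.45 to 5.32, adjusted p = 1.82e-07). The highest intensity on any array was 58725 to 64685, not far above its treated level. In atf3, at Zv7 chromosome 20, 25189669 to 25195773, log2 intensity went from 10.22 ± 0.40 to 14.05 ± 0.17 (adjusted p = 9.73e-06). The other leading rises were in cbx7a, a Polycomb subunit (log2 3.57, SE 0.25), stmn4l, a stathmin of the microtubule regulators (3.29, SE 0.19), fosl1a (3.15, SE 0.23), kcnn4, a calcium-activated potassium channel (3.05, SE 0.32), and atf5a (2.83, SE 0.32). Behind them came the interferon-stimulated gene isg15 (2.68), the glycolytic regulator pfkfb3 (2.67), the kinase gene mknk2b (2.63), the stress-induced sesn2 (2.53), the rhomboid protease gene rhbdd1 (2.47) and arginase arg2 (2.46). Adjusted p-values of these 12 genes ran from 6.96e-06 to 0.00304. The second feature of fosl1a had a log2 difference of 1.05 and was not called (adjusted p = 0.205).

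Among the 17 measured genes of the ER stress and amino acid starvation list, 6 rose and 1 fell, or 7 and 3 with p adjusted over the list alone. The risers were atf3, sesn2, ddit3 (log2 2.15), the pseudokinase trib3 (2.45), cebpg (1.43) and cebpb (1.56), which are regulators of transcription or signalling. The member that fell, pdia4, is a protein-folding enzyme of the ER (-1.09, adjusted p = 0.0296, chosen after its values were seen), and the ER chaperone hsp90b1 stood at -0.63 (adjusted p = 0.214). The list as a whole rose (median 0.45, adjusted p = 2.8e-06, and adjusted p = 0.112 with an estimated correlation). Immediate early genes rose with a median of 0.51 (adjusted p = 2.09e-06, and adjusted p = 0.06 with an estimated correlation). Of 16 members, 4 rose, namely atf3, fosl1a, jun (log2 1.92) and the cytokine-signalling inhibitor socs3a (2.01), or 6 adjusted over the list alone. Inflammation genes rose (18 measured, median 0.42, adjusted p = 4.06e-07, and adjusted p = 0.0756 with an estimated correlation). There 3 members rose, or 6 adjusted over the list alone, with socs3a, cebpb and the matrix metalloproteinase mmp9 (2.09, adjusted p = 0.0192), while il1b stood at 1.17 (adjusted p = 0.0519). The p53 and apoptosis list rose with either correlation (13 measured, median 0.46, adjusted p = 2.09e-06, and adjusted p = 0.0229 with an estimated correlation). The pro-apoptotic bbc3, which encodes Puma, rose by 2.18 log2 units, and 5 members passed adjusted over the list alone. Initiator caspase casp9 stood at 1.34 (adjusted p = 0.0639) and mdm2 at 0.64 (adjusted p = 0.19). The 3 genes atf3, cebpb and socs3a each sit on 2 of these lists.

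**Figure D1:**
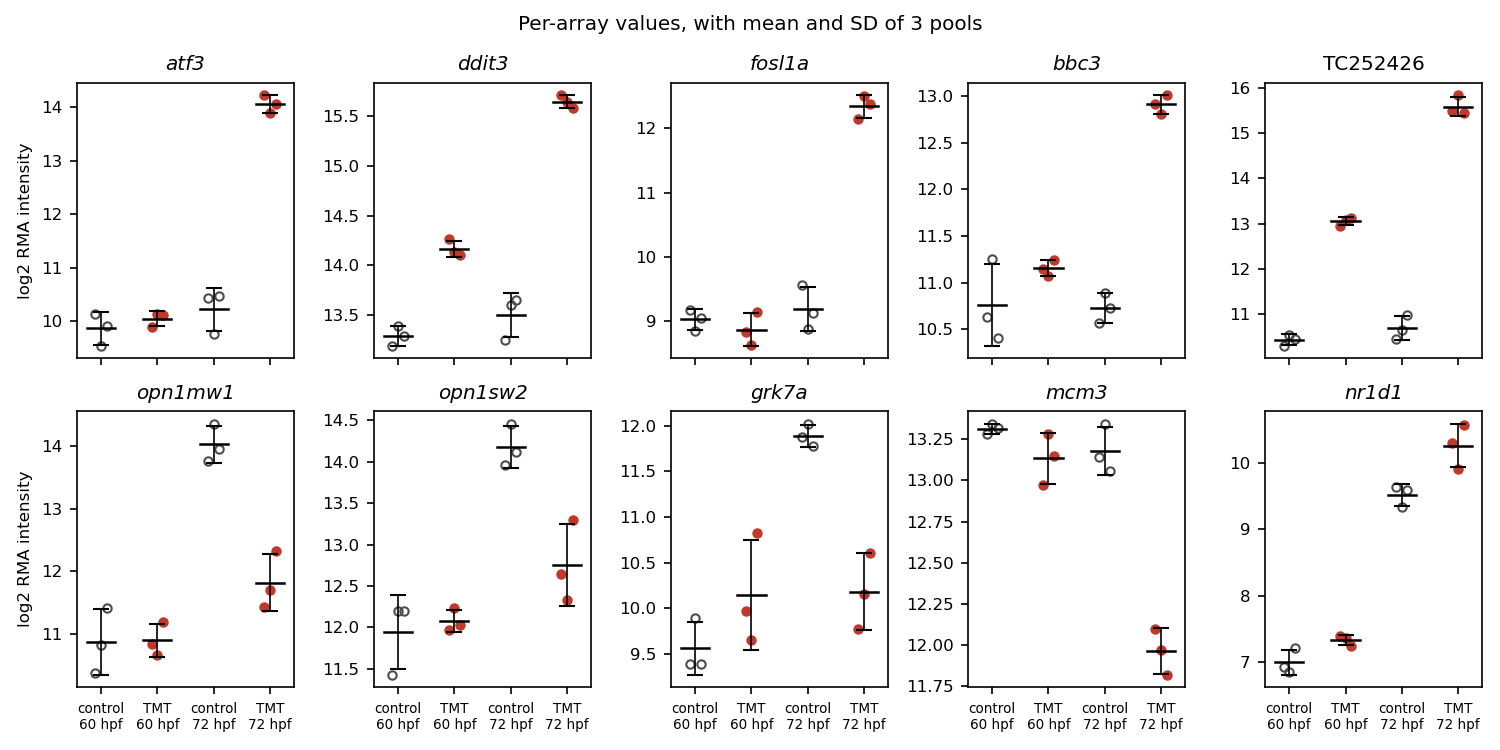
Log2 RMA intensity (vertical axes, not starting at 0) of 10 features in each pool of the 4 groups (control and TMT at 60 and 72 hpf), with points for the 3 pools and bars for the mean ± SD. The contig TC252426 lay above control at both ages, atf3 at 14.05 against 10.22 at 72 hpf, and opn1mw1 at 11.82 against 14.03 at 72 hpf.

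Photoreceptor genes formed the list with the largest median fall. Of 27 measured, 22 lay below control, with a median of -0.79 (adjusted p = 3.36e-11, and adjusted p = 0.0757 with an estimated correlation). The fall was called for 5 genes, or 15 adjusted over the list alone. The 5 were opn1mw1 at Zv7 chromosome 6, 21531177 to 21533131 (log2 -2.21, SE 0.31, adjusted p = 0.0032), the cone kinase grk7a (-1.71), the opsin kinase grk1b (-1.66), the blue opsin opn1sw2 (-1.42) and the red opsin opn1lw2 (-1.30). Lens genes had a median of -0.03 over 30 members and were not shifted (adjusted p = 0.833). Genes of synapses and mature neurons also fell (36 measured, 31 below control, median -0.43, adjusted p = 1.03e-08, and adjusted p = 0.0756 with an estimated correlation). The complexin cplx2 (-1.12, adjusted p = 0.0156) and the glycine transporter slc6a5 (-1.20, adjusted p = 0.0226) fell, as did 10 members adjusted over the list alone. A single member passed the other way, the stathmin stmn4, which rose by 1.76 (adjusted p = 0.000837). Outside the lists, falls were largest in the D-amino acid oxidase dao.1 (log2 -2.19), the cytochrome P450 cyp2aa8 (-1.89), exoc1l (-1.78), spam1 (-1.66), the cartilage protein mia (-1.60), glucokinase gck (-1.52) and the nicotinic receptor subunit chrna6 (-1.42). Adjusted p-values of the 12 leading falls ran from 0.0032 to 0.0333.

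Cell cycle and DNA replication genes fell together. Of 24 measured, 23 lay below control (median -0.42, adjusted p = 3.36e-08, and adjusted p = 0.122 with an estimated correlation). The replicative helicase subunits mcm3 (log2 -1.22, adjusted p = 0.00534) and mcm5 (-1.23, adjusted p = 0.0349) were called, and 4 members adjusted over the list alone. Proteasome genes fell (28 measured, median -0.24, adjusted p = 5.62e-05, and adjusted p = 0.152 with an estimated correlation), with no member past the threshold and 2 adjusted over the list alone, where psmd8 stood at -0.81. Liver products fell (22 measured, 21 below control, median -0.27, adjusted p = 0.00332, and adjusted p = 0.349 with an estimated correlation), and no member passed alone in either adjustment. The liver fatty acid binding protein fabp10a stood at -0.82 (adjusted p = 0.251).

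Clock genes rose (24 measured, 22 above control, median 0.57, adjusted p = 1.6e-08, and adjusted p = 0.0356 with an estimated correlation). The repressor nfil3 passed (log2 1.11, adjusted p = 0.0154), 4 members passed adjusted over the list alone, and cry2 stood at 0.88 (adjusted p = 0.0501). The stress hormone list rose too (17 measured, median 0.38, adjusted p = 2.52e-05, and adjusted p = 0.0229 with an estimated correlation). Of its members, klf9 (1.51), igfbp1a (1.64) and the kinase sgk1 (0.95) were called, and 6 passed adjusted over the list alone. Another member, fkbp5, stood at 0.22 and was singled out after its values were seen. Pigment cell genes rose (15 measured, median 0.42, adjusted p = 0.0072, and adjusted p = 0.192 with an estimated correlation) with 0 members called and 3 adjusted over the list alone. Cholesterol and fatty acid synthesis rose (21 measured, median 0.22, adjusted p = 0.0182, and adjusted p = 0.3 with an estimated correlation). Its called members were the lipoprotein receptor ldlra (1.36) and insig1 (1.08), which restrains sterol synthesis, and 3 passed adjusted over the list alone. Metal response genes rose (8 measured, median 0.33, adjusted p = 0.0238, and adjusted p = 0.112 with an estimated correlation), with 0 members called and 1 adjusted over the list alone. Ribosomal protein genes rose slightly (46 measured, median 0.10, adjusted p = 0.0486, and adjusted p = 0.702 with an estimated correlation), with 0 members called in either adjustment. The ribosomal call was lost with the replicate block (adjusted p = 0.0539) and with the random-probe level as a covariate (adjusted p = 0.207), and those of the pigment cell (0.0907) and cholesterol lists (0.0917) with only the brighter features. Without control pool 3 the calls of the pigment cell (adjusted p = 0.118), cholesterol (0.195), metal response (0.05) and ribosomal lists (0.236) were lost. The metal response call was also lost without control pool 2 (0.066), the cholesterol call without TMT pool 3 (0.0803) and the ribosomal call without TMT pool 1 (0.688) or 3 (0.271).

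The other 22 lists were not shifted at 72 hpf. Heat shock genes (20 measured, adjusted p = 0.151) held 1 called member, the chaperone hsp90aa1.1, which fell (log2 -1.10, adjusted p = 0.0249), while hsp70.3 stood at 0.84 (adjusted p = 0.0514). The hypoxia list (18 measured, adjusted p = 0.0525) held pfkfb3 and igfbp1a as its 2 risers. Erythroid cells (12 measured, adjusted p = 0.103) and glia (15 measured, adjusted p = 0.258) shared a single called member, the carbonic anhydrase cahz (log2 -1.04, adjusted p = 0.0478). The xenobiotic list (13 measured, adjusted p = 0.708) held the transporter abcc2, which rose by 1.04 (adjusted p = 0.0492). No member of any remaining list was called by limma over all features. Their adjusted p-values were 0.215 for oxidative stress (13 measured), 0.623 for neutrophils and macrophages (13), 0.258 for vascular endothelium (20), 0.727 for ADP-ribosylation factors (15), 0.708 for glycolysis (15) and 0.577 for oxidative phosphorylation (20). They were 0.623 for neural progenitors (21), 0.708 for skeletal muscle (32), 0.562 for cardiac muscle (17), 0.232 for cartilage and bone (19), 0.833 for extracellular matrix (22) and 0.973 for epidermis and ionocytes (29). For pancreas (21) the value was 0.763, for intestine (18) 0.708, for kidney (15) 0.228 and for retinoid and RXR/PPAR targets (31) 0.232. In the xenobiotic and epidermis lists the median was negative while the test pointed up, and in the extracellular matrix list the reverse held. The ADP-ribosylation factor and pancreas lists also pointed up with a negative median. Adjusted over the list alone, 3 erythroid and 2 glial members fell, as did 1 vascular, 2 retinoid target and 1 heat shock member, while 1 heat shock, 1 kidney, 1 neural progenitor, 1 xenobiotic and 2 hypoxia members rose. In the same way 2 ADP-ribosylation factors rose and 1 fell, and 1 pancreas member went each way.

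**Figure D2:**
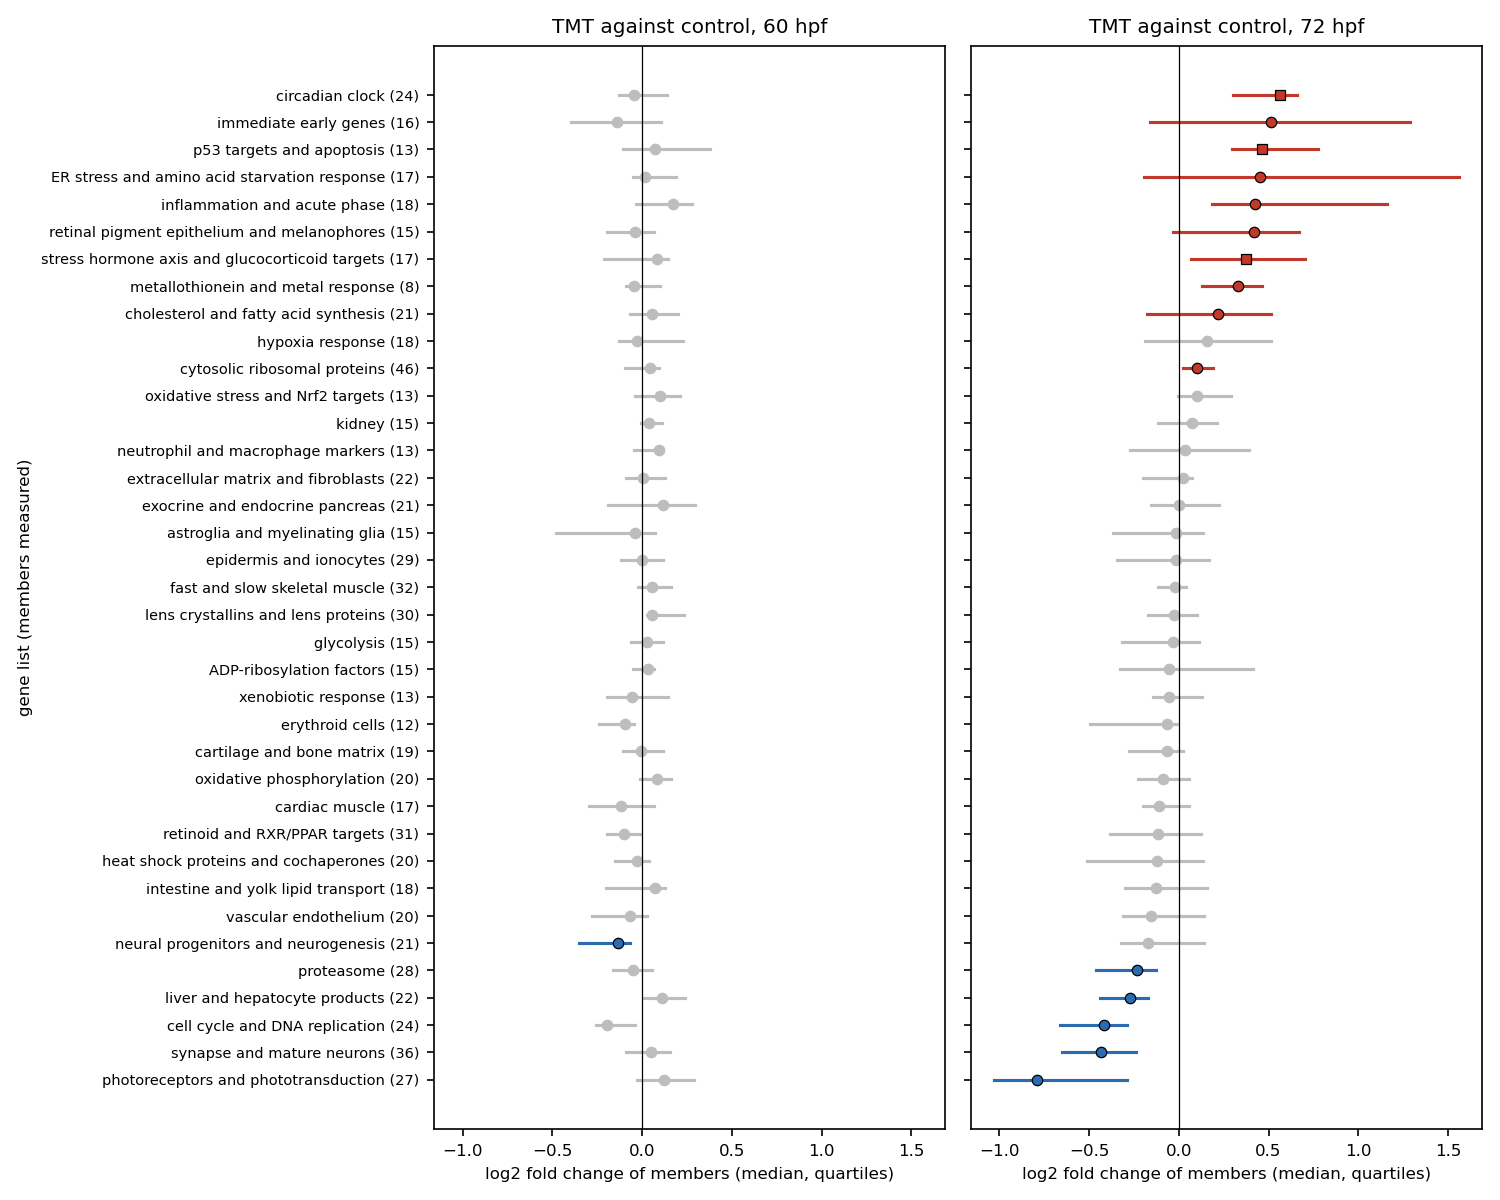
Median log2 effect of TMT (horizontal axis) and quartiles (bars) for the 37 gene lists at 60 and 72 hpf. Coloured markers passed camera at the preset correlation, squares also with an estimated correlation, which at 72 hpf held for 3 of 15 lists.

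The count at 72 hpf was lower whichever array of that age was left out, which leaves 2 pools in a group. It was 216, 170 and 203 without control pool 1, 2 or 3, and 204, 299 and 151 without TMT pool 1, 2 or 3. A loss of precision with fewer pools and a dependence on particular arrays were not told apart. Of the 48 called features that the naming rule took or that were singled out, 16, 19 and 14 lost their call without control pool 1, 2 or 3 and 17, 10 and 20 without TMT pool 1, 2 or 3. The 23 that lost it at least once were grk7a, opn1sw2, opn1lw2, spam1, gck, cyp2aa8, chrna6, mcm5, cplx2, slc6a5, hsp90aa1.1, pdia4, cahz, mmp9, igfbp1a, klf9, sgk1, nfil3, ldlra, insig1, abcc2, cebpg and cebpb, whose highest adjusted p over the alternatives ran from 0.0522 to 0.205. The other 25, namely the contig, the 12 leading risers, opn1mw1, dao.1, exoc1l, grk1b, mia, mcm3, ddit3, trib3, bbc3, jun, socs3a and stmn4, were called under every alternative that tested them.

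Whether the response differed between the ages was tested as the difference between the 2 effects. The largest differences in named genes were in atf3 (log2 3.64, adjusted p = 0.00226), kcnn4 (3.61, adjusted p = 0.0138), fosl1a (3.31, adjusted p = 0.00226), cbx7a (3.25, adjusted p = 0.0034), atf5a (2.88, adjusted p = 0.0353) and stmn4l (2.77, adjusted p = 0.00226). The contig similar to ADP-ribosylation factor 1, which rose at both ages, also rose more at 72 hpf (2.27, adjusted p = 0.0138). For ddit3 the difference was 1.27 (adjusted p = 0.113) and for opn1mw1 -2.24 (adjusted p = 0.0952). In total 46 features had a positive difference and 0 a negative one in limma's test. At an unadjusted p below 0.05 these were 1380 and 860. A negative difference can be a deeper fall at 72 hpf, as in opn1mw1, and need not be a smaller effect.

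Of the lists, 12 differed between the ages, 7 upward and 5 downward. Immediate early genes (median difference 0.57, adjusted p = 1.66e-08, and adjusted p = 0.0443 with an estimated correlation), p53 targets (0.33, adjusted p = 0.000453, and adjusted p = 0.0487 with an estimated correlation) and the stress hormone list (0.51, adjusted p = 0.000138, and adjusted p = 0.0443 with an estimated correlation) did so in either test. Photoreceptors (-0.82, adjusted p = 2.11e-14) and synapse genes (-0.43, adjusted p = 8.27e-10) had adjusted p = 0.056 each with an estimated correlation. The count of 46 moved with every array left out. It was 7, 81 and 12 without control pool 1, 2 or 3 of 60 hpf, 11, 6 and 16 without TMT pool 1, 2 or 3 of 60 hpf, 7, 15 and 19 without control pool 1, 2 or 3 of 72 hpf, and 14, 18 and 10 without TMT pool 1, 2 or 3 of 72 hpf. Of 11 named features called for this difference, atf3, cbx7a, stmn4l and fosl1a kept the call with each array left out in turn, and kcnn4, atf5a, mknk2b, rhbdd1, trib3, jun and the contig lost it at least once (highest adjusted p over the alternatives 0.0554 to 0.126). Without TMT pool 2 of 60 hpf all 7 of these were lost.

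Control embryos of 72 and 60 hpf were compared to describe the developmental background. The 2 collections lay 12 h apart, and no time of day was used here, so a daily rhythm cannot be told apart from age. Genes of photoreceptors were among those with the largest rises with age, led by the outer segment protein prph2b (log2 3.35, adjusted p = 0.00272), opn1mw1 (8.98-fold, adjusted p = 0.00054), the cone phosphodiesterase pde6c (8.78-fold, adjusted p = 0.00118), the arrestin arr3b (6.94-fold, adjusted p = 0.000323), rcvrn3 (6.12-fold, adjusted p = 0.00272) and pde6hb (5.62-fold, adjusted p = 0.00588). The pancreatic protease prss59.1 (8.48-fold, adjusted p = 0.000282) and the clock repressor nr1d1 (5.77-fold, adjusted p = 0.000297) rose as well. The embryonic globin hbbe3 (log2 -2.45, adjusted p = 0.0196), the hatching enzymes he1 (-2.44, adjusted p = 0.00371) and he1.2 (-1.69, adjusted p = 0.0064), and gad3 (-1.29, adjusted p = 0.0209) fell, and were the only 4 falls the naming rule allowed. Of 38489 features 101 rose and 16 fell.

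The photoreceptor list rose with age (27 measured, 11 risers, 23 adjusted over the list alone, median 1.11, adjusted p = 1.72e-43), as did the clock list (24 measured, 8 risers, 11 adjusted over the list alone, median 0.41, adjusted p = 3.52e-13). For the clock list, age and time of day cannot be separated. Neural progenitors fell (21 measured and all below 60 hpf, 0 called, 9 adjusted over the list alone, median -0.58, adjusted p = 6.9e-15). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.00899 each), and 12 others did not. Those 12 had adjusted p-values up to 0.0411 at the preset correlation. Synapse genes (median 0.29), pancreas (0.22), liver (0.15), intestine (0.29), cholesterol synthesis (0.20), inflammation (0.06) and oxidative stress (0.14) rose, and erythroid (-0.26), cell cycle (-0.34), pigment cell (-0.33), ribosomal (-0.11) and vascular genes (-0.12) fell, with adjusted p = 0.0608 to 0.613 with an estimated correlation. The count of 117 was 75 without control pool 1 of 60 hpf and 52 without control pool 2 of 72 hpf, where the call of he1.2 was lost, as were those of hbbe3 (adjusted p = 0.141) and gad3 (adjusted p = 0.161). The call of hbbe3 was also lost without pool 2 or 3 of 60 hpf or pool 1 or 3 of 72 hpf, and that of gad3 without pool 1 or 3 of 60 hpf or pool 3 of 72 hpf, at lower adjusted p-values. With only the 6 control arrays in the fit the count was 47, and the calls of gad3, he1 (adjusted p = 0.0695) and he1.2 (adjusted p = 0.08) were lost.

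**Figure D3:**
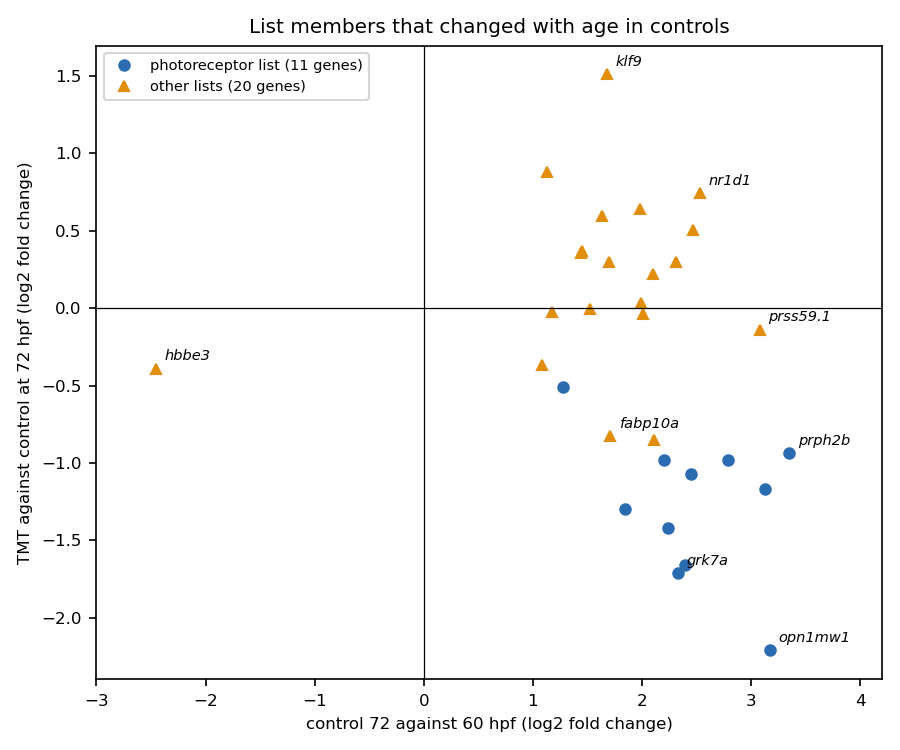
Log2 effect of TMT at 72 hpf (vertical axis) against the log2 change from 60 to 72 hpf in controls (horizontal axis) for list genes that changed with age, 11 photoreceptor genes and 20 genes of other lists. All 11 photoreceptor genes rose with age and lay below 0 after TMT, and the 72 hpf controls enter both axes.

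Across features, which are not independent replicates, the effects of TMT at the 2 ages correlated weakly (Pearson 0.117, Spearman 0.117). Of 100 drawn regroupings of the arrays, 60 gave a Pearson as far from 0. It was 0.0113 without control pool 3 of 60 hpf, -0.00733 without control pool 1 and 0.177 without control pool 3 of 72 hpf, and 0.0761, 0.190 and 0.0498 without TMT pool 1, 2 or 3 of 72 hpf. Of the 331 features that rose at 72 hpf, 70.4% lay above control at 60 hpf, against 46.0% of the features not called. Of the 86 that fell, 67.4% lay below control at 60 hpf, against 54.0%. Other divisions of the 6 arrays at 60 hpf reached 80.4% and 83.7% on 1 side. The effect of TMT at 72 hpf correlated negatively with the control change from 60 to 72 hpf (Pearson -0.176, Spearman -0.171). Because the 72 hpf controls enter both, simulations with no effect gave -0.499. The Pearson was -0.0863 without control pool 2 of 60 hpf, and -0.358 and -0.292 without control pool 1 or 3 of 72 hpf. The covariance was -0.0236, against -0.0546 simulated, a difference of 0.031, and the 3 controls could not be split with 2 in each part. The simulation drew arrays independently, with 1 spread per feature for all groups. The 72 hpf controls, which alone set the simulated covariance, had the smallest median standard deviation of the groups (0.254). The difference may therefore be overstated, and nothing was concluded from it. The change with age in TMT pools correlated with that in control pools (Pearson 0.346). These 3 relations between contrasts were the only ones computed across features.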

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

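The counts under other splits of the arrays were planned, and all the other tests of explanations below were chosen only after the result was seen. The effects of TMT at 72 and 60 hpf were set against each other in the limma fit. The items here are those where the difference passed, 46 features in total, all with a positive difference. Among named genes the log2 difference was 3.64 for atf3, 3.25 for cbx7a, 2.77 for stmn4l, 3.31 for fosl1a, 3.61 for kcnn4, 2.88 for atf5a, 2.35 for mknk2b, 2.2 for rhbdd1, 2.69 for trib3, 1.74 for jun and 2.27 for the contig TC252426. Of 100 drawn splits of the arrays of both ages, 6 gave at least 46 features and the highest other gave 169, so chance was not excluded by the count. All 6 keep the real division at 72 hpf, and the 93 splits with another division there gave at most 5. With the 72 hpf labels as in the study, the split with 169 exchanges control pools 2 and 3 with TMT pools 2 and 3 at 60 hpf. Its count, several times the real one, points to a structure of the samples, which was not tested. Without control pool 1 of 60 hpf the count was 7, without TMT pool 1 of 60 hpf 11, and without control pool 2 of 60 hpf 81.

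The gene lists that differed between the ages had these median log2 differences. The immediate early list had 0.567, the stress hormone list 0.511, the circadian clock list 0.487, the pigment cell list 0.420, the ER stress list 0.394, the p53 list 0.329 and the inflammation list 0.181. The photoreceptor list had -0.816, the liver list -0.444, the synapse list -0.434, the cell cycle list -0.318 and the proteasome list -0.292. With an estimated correlation only the immediate early, p53 and stress hormone lists were called (adjusted p = 0.0443, 0.0487 and 0.0443).

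Photoreceptor genes were lower after TMT at 72 hpf. A general delay of development was tested with each 72 hpf control pool in turn giving the TMT effect and the others the age change. It took the place of a first test on single genes that used the same controls for both. The values were averaged over the turns, so every control pool still enters both averages, and their shared noise was not removed. The photoreceptor list was missing 64.5% of its age change. The same share would put the neural progenitor list, which falls with age, 0.386 above control, but its median was -0.139. The 95% bootstrap interval of -0.284 to 0.0834 was drawn over the list's 21 genes and not over pools, so it leaves out the spread between pools. The value argues against a delay of all tissues alike only if TMT does not itself lower this list, which fell at 60 hpf. The synapse (-0.421, age change 0.286), liver (-0.309, age change 0.153), pigment cell (0.377, age change -0.375) and ribosomal (0.109, age change -0.135) lists moved back toward 60 hpf with each control pool. The synapse and liver effects were larger than the age change. The cell cycle (-0.47), clock (0.535), inflammation (0.499), cholesterol (0.225), erythroid (-0.186) and neural progenitor lists moved back with none of the pools. The oxidative stress, vascular, pancreas and intestine lists did so with some. A delay of some tissues thus stays open, as does a response of photoreceptors to TMT, and either may account for the pattern. The lens list (median -0.0287, quartiles -0.171 and 0.101) argued against less tissue of the whole eye, lens included. It cannot speak to a smaller retina or fewer photoreceptor cells, which it does not measure, so these stay open too. A difference in background was argued against by the photoreceptor median of -0.742 with the random-probe level in the fit (camera adjusted p = 9.32e-11), against -0.789 without it.

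More features changed at 72 than at 60 hpf. A larger spread at 60 hpf alone would leave effects of the same size, so features were called at 72 hpf without 1 control and 1 TMT pool and their effect at 72 hpf was read from the pair left out, which removes the gain from selection in a first test it replaced. Over the 9 pairs, 65 to 104 features rose, with medians of 2.02 to 2.3 in the left-out pair and of 0.217 to 0.313 at 60 hpf. Leaving out the 60 hpf control array with the highest random-probe level gave 1 feature, against 417 at 72 hpf. The longer exposure, the greater age of the embryos and any difference in time of day go together in the design. Each could account for the pattern, and none was tested.

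The contig similar to human ADP-ribosylation factor 1 was higher after TMT at both ages. A rise of the whole family of these factors as large as that of the contig was argued against. The other 23 features tied to that human gene or on the list had a median of 0.0838 (quartiles -0.303 and 0.416), against 4.88 for the contig, and none was called. The list also holds the related arl genes, so this median says little about smaller rises of single arf genes. A first form of this test bounded the highest of them, and it was replaced after the values were seen because that value, 1.35, exceeded the bound. The outcome of the new form was thus known when it was set, so its values are only descriptive. A difference in background was argued against by effects of 4.91 at 72 hpf and 2.64 at 60 hpf (adjusted p = 0.000536) with the random-probe level in the fit. A transcript induced by TMT may account for the pattern as a hypothesis, and the identity of the contig was not tested.

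The other planned splits of 6 arrays into 3 and 3 number 10 for each count, which is too few for a share under 0.05. At 60 hpf the real value was 1 feature and the highest other 8 (2 of 10 splits gave as many), and for lists 1 against 4 (8 of 10 splits). At 72 hpf the real value was 417 features and the highest other 0 (1 of 10), and for lists 15 against 10 (1 of 10). For the control ages the real value was 117 features and the highest other 0 (1 of 10). Every other split at 72 hpf called lists at the preset correlation, from 2 to 10, and those at 60 hpf called 0 to 4. Lists were thus often called without the real division, which limits the list calls at the preset correlation. Each other split keeps part of the real contrast, so no rate of false calls follows.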

How the results depend on the processing

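The covariate was chosen after seeing the data, and the other alternatives were planned. Where no reason is given, the cause was not tested. Of 20530 values of single named genes under an alternative, 20108 stayed on the same side of the threshold, 636 of them uncalled with the other sign, while 247 lost a call, 175 gained one and 0 were called in the opposite direction in limma's test. Of 85 such calls 43 were kept under every alternative.

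At 60 hpf, 1 feature was called, and 2 with a further quantile normalization, with centring and with array weights, and 0 with 1 feature per gene, by construction, since the contig has no gene name. At 72 hpf the count of 417 (331 higher, 86 lower) became 241 (217 and 24) with only the arrays of the groups compared, which are fewer, 230 (202 and 28) with the replicate block, 721 (456 and 265) with only the brighter features, 698 (480 and 218) with trend and robust moderation, 1367 (749 and 618) with array weights, 188 (143 and 45) with 1 feature per gene, where fewer are tested, and 654 (489 and 165) with the random-probe covariate. Array weights and the covariate each kept all 417, and moderation 403. For the difference of the effects, 46 became 5 with the replicate block, 80 with moderation, 121 with array weights and 17 with 1 feature per gene. For the control ages, 117 became 47 with only the groups compared, 77 with the replicate block, 186 with array weights and 74 with 1 feature per gene. For these counts of features, the other planned settings that kept all arrays of the contrast stayed within 1.5 times. Lists called at 60 hpf were 1, and 0 with an estimated correlation and 2 with the mean of a gene's features, and at 72 hpf 15 became 3 with an estimated correlation.

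With each array left out, counts ran from 1 to 2 features at 60 hpf, 151 to 299 at 72 hpf, 6 to 81 for the difference and 52 to 121 for the control ages, and lists at 60 hpf from 1 to 6. The correlation of the 2 effects ran from -0.00733 (without control pool 1 of 72 hpf, a reversed sign) to 0.190, and that of the effect at 72 hpf with the control change from -0.358 to -0.0863. Signal over background limits dim features, since 90.2% to 98.9% of features lay above the random probes. Replicate numbers gave no general pairing of pools, as 3 of 18 same-number correlations of deviations exceeded 0.1, the highest at 0.432. Pools with different numbers in different groups also shared deviations, up to 0.537 for TMT pool 1 of 60 hpf and control pool 3 of 72 hpf. The arrays thus share structure that the main fit does not include.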

Other observations

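Genes called both for TMT at 72 hpf and for age in controls included genes that are not on the photoreceptor list. Glucokinase, gck, rose by 1.63 log2 units from 60 to 72 hpf in controls and fell by 1.52 after TMT, while the transcription factor klf9 rose by 1.68 with age and by 1.51 after TMT. Each of these 4 calls was lost under some alternatives, with a highest adjusted p of 0.302 for age and 0.163 for TMT in gck, and of 0.174 for age and 0.132 for TMT in klf9. The 72 hpf controls enter both contrasts with opposite sign, so noise in them alone could give opposite changes such as those of gck. Among named ADP-ribosylation factors, arf4a stood at 1.35 (adjusted p = 0.0534), arf5 at 0.81 (adjusted p = 0.069) and arf3a at -0.99 (adjusted p = 0.0797) at 72 hpf, and none of them passed.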
